A study of Mus musculus with 6 samples.

How the data were processed

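Poly(A) RNA of mouse 2-cell embryos was sequenced in 2 groups of 3 libraries, control and 5 µM sodium arsenite. Groups and replicate numbers were taken from the sample labels. The deposited values are whole read counts per gene symbol, not normalized, with a column per library. The submitters' processing notes name the build mm10, STAR, StringTie 2.1.4, featureCounts 1.6.2 and DESeq2 1.30.1, without the role of each. The version of STAR, the gene annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands and reads shared between copies limit single values. Per the labels' protocols cDNA was preamplified by PCR, with no molecular identifiers mentioned, and their text describes a pair of different library kits, so the kit used is uncertain.

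The table held 18660 rows, and 0 of them had 6 counts summing to under 2. In 11 rows the symbol had become a calendar date. These rows took 0.0432% to 0.0818% of a library's counts and were left out. Total counts were 8519265, 7830516 and 8121485 in control replicates 1, 2 and 3 and 8324235, 8391579 and 7758507 in arsenite replicates 1, 2 and 3. A floor of 3 counts was 0.352 to 0.387 CPM of a library. Mitochondrially encoded genes were not analysed here. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 34.6. Spearman correlations across genes, which are not independent replicates, were 0.925 to 0.946 within controls, 0.899 to 0.931 within arsenite libraries and 0.806 to 0.880 between groups.

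Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr defaults, two-sided quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05), arsenite against control with no covariate. This tested 12582 genes, with a common biological coefficient of variation of 0.495. CPM are scaled by TMM. The test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added later. Lists were matched by symbol. The 25 lists with at least 5 tested members went through two-sided camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over these lists, and also through camera with an estimated correlation and fry. None of the 8 lists past the threshold kept its call with an estimated correlation. Library composition was compared by exact two-sided permutation tests, in which the shares of Spin1 and Rn45s and a sign-flip test within numbered pairs were added after the data were seen.

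The rule for named genes took genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a symbol other than a Gm number or a Rik clone, and of these the 6 largest rises and 6 largest falls. It also took the 2 members of each list with the smallest p, or 4 for the maternal, 2-cell, NRF2 and acetyltransferase lists, and Hmox1, Mt1, Mt2, Zscan4d, Zfp352, Ep300, Crebbp, Nanog and Pou5f1. Other genes are named as chosen after their values were seen, and 1 gene that the rule took and 1 gene family are not reported here. Positions are RefSeq genes on GRCm38.p6, the assembly behind mm10. Transcript length, GC content and 3' UTRs came from GENCODE M21.

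The shared replicate numbers were checked for pairing. Deviations from group means, across genes, correlated at 0.189, 0.221 and 0.178 for same-numbered libraries and between −0.164 and −0.0238 for the others. With each same-numbered pair over 0.1, the numbers were taken to pair the libraries, although the labels do not say what a number shares. Genes are not independent and 3 libraries a group allow few matchings, so this matching could be the highest by chance. Deviations within a group sum to 0, so the negative values follow in part from the positive ones and are no separate support. The edgeR fit without a covariate, fixed before this check, ignores the numbers. The fit with the number as a block was an alternative.

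The tests were checked on simulated data of 12582 genes, in 5 runs with 200 changed genes each. With 3 libraries a group edgeR recovered 5.6% of genes changed 2-fold, 43.6% at 4-fold, 74.4% at 8-fold and 86.4% at 16-fold. Of its calls 6.91% were false, above the nominal level, against 5.88% with voom and 24.1% with DESeq2 1.42.0. Camera made 5 list calls, 0 of them false, on genes simulated without correlation between them. Alternatives were other scalings, count filters, tests and list tests, the block, a 2-fold limit, leaving out each library, and leaving out the 20 most abundant genes. Keeping the date rows and removing trends with length and GC were added after the data were seen.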

Results

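Poly(A) RNA from mouse embryos at the 2-cell stage was sequenced in 3 control libraries, labelled 0 µM, and in 3 libraries from embryos given G1-PLUS medium with 5 µM sodium arsenite, a trivalent arsenic salt. The count table held whole read counts for 18660 named rows. Library totals lay between 7758507 counts (arsenite replicate 3) and 8519265 counts (control replicate 1). The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads amplified by PCR without molecular identifiers are not independent molecules, so counting floors and intervals cover counting error only. The single comparison asks how arsenite alters the transcriptome at the stage when stored maternal RNA gives way to transcripts of the embryo's own genome.

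Of 85 tested maternal and oocyte transcripts 52 were higher with arsenite than in controls, and of 111 ribosome biogenesis factors 47 were lower (edgeR adjusted p under 0.05). As lists both passed camera, a test of gene sets, at a preset correlation but not with an estimated correlation (adjusted p = 0.453 and 0.0642). Btg4, an adaptor that brings a deadenylase to maternal mRNA, rose from 725 ± 237 to 4431 ± 1466 CPM (SD, n = 3 each), where CPM are counts scaled to library size. Rpf2, which helps load 5S RNA onto the large ribosomal subunit, fell from 586 ± 44.9 to 124 ± 40.8 CPM (SD, n = 3 each). Of 12582 genes tested, 1187 rose and 914 fell with arsenite, 2101 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold made up 1167 of the rises and 882 of the falls. The 3 arsenite libraries lay entirely above or below the 3 controls for 5231 tested genes (41.6%), where chance gives 10%, and for every gene named below as having risen or fallen. With the replicate number as a block 3268 genes were called, 1682 higher and 1586 lower. Without control replicate 1, 2 or 3 the calls numbered 1079, 1096 and 405, and without arsenite replicate 1 they numbered 506. Such fits hold fewer libraries, so a call lost in them need not mean a smaller change. Scaling by library size only, which moved the median log2 fold change of all genes from 0.07 to −0.05, called 930 higher and 1070 lower, so directions here are relative to the TMM scale. Rises were 56.5% of calls, but 46.5% with that scaling and also without arsenite replicate 2, 44.0% with a trend on length and GC content removed (1136 higher, 1448 lower) and 42.1% with that and the block.

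**Figure D1:**
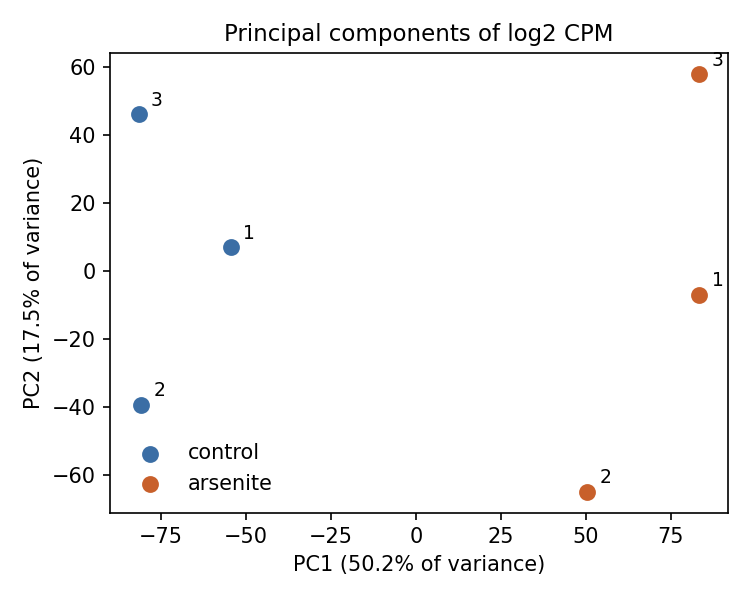
Principal components 1 and 2 of log2 CPM over the tested genes, in arbitrary units, with 1 point per library and its replicate number beside it. Component 1 (50.2% of the variance) placed controls between −81.6 and −54.4 and arsenite libraries between 50.4 and 83.4, and component 2 carried 17.5%.

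Library makeup differed between the groups too. Cytosolic ribosomal protein genes took 2.18 ± 0.464% of counts in controls and 0.944 ± 0.437% with arsenite (SD, n = 3 each). The 50 most abundant genes took 13.5 ± 0.832% and 18.96 ± 1.31% (SD, n = 3 each). Spin1, a histone reader chosen after its values were seen, took 0.546 ± 0.151% and 2.35 ± 0.630% (SD, n = 3 each). For each of these 3 shares the groups did not overlap, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give, and 0.2 after Benjamini-Hochberg adjustment over 6 measures. The ribosomal RNA precursor Rn45s, also chosen after its values were seen, took 0.997 ± 0.405% and 0.450 ± 0.205% (SD, n = 3 each, exact permutation p = 0.2, adjusted p = 0.24). Genes with at least 1 count numbered 15021 ± 387 in controls and 15765 ± 693 with arsenite (SD, n = 3 each, exact permutation p = 0.2, adjusted p = 0.24). Total counts had an exact permutation p of 1. Within each of the 3 pairs of libraries with the same number, the arsenite library had the lower share of Rn45s and of ribosomal protein genes and the higher number of genes, share of the top 50 and share of Spin1. An exact two-sided sign-flip test of these pairs, added after the data were seen, gave p = 0.25 for each, the smallest that 3 pairs allow.

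Of 85 tested maternal and oocyte transcripts 52 rose, 0 fell and 33 did not pass the edgeR test, while 61 rose and 1 fell adjusted over the list alone. Rfpl4, an oocyte RING finger gene (chromosome 7, 5109787 to 5116911, mm10), rose from 202 ± 54.9 to 1617 ± 589 CPM (SD, n = 3 each), a log2 fold change of 3.00 ± 0.38 (SE, edgeR adjusted p = 0.00416). The oocyte homeobox genes Obox1 (chromosome 7, 15547257 to 15556846) and Obox2 rose by 3.07 ± 0.41 and 2.87 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.00447 and 0.00416). Nlrp4e, of the NLR family, rose from 78.6 ± 26.9 to 439 ± 32.0 CPM (SD, n = 3 each, edgeR adjusted p = 0.00416). Obox genes have near-identical copies, so the value of a single copy is uncertain. The list median was 1.75, past the threshold by camera (adjusted p = 7.86e-13). The call was lost at an adjusted p = 0.453 with an estimated correlation. The estimated correlation between members was 0.251 here, against the preset 0.01. Without control replicates 1, 2 and 3 in turn 38, 30 and 23 members rose, and without arsenite replicates 1, 2 and 3 in turn 26, 50 and 49. The cumulus cell marker Cyp11a1 was also higher, with 0 counts in controls and 62 with arsenite. A link between it and these transcripts was not tested.

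Of 37 tested factors that degrade maternal mRNA 9 rose and 0 fell, while 9 rose and 1 fell adjusted over the list alone. Btg4 (chromosome 9, 51102147 to 51119924) rose by 2.61 ± 0.38 and Pan3, a subunit of a poly(A) nuclease, by 1.64 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 0.00485 and 0.0112). Pan3 lost its call without control replicate 3 (edgeR adjusted p = 0.0584). These factors had a median of 0.46 and camera did not pass (adjusted p = 0.143). With the block 3 members fell. Leaving out control replicates 1, 2 and 3 in turn left 5, 5 and 1 rises, and leaving out arsenite replicates left 2, 9 and 6.

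**Figure D2:**
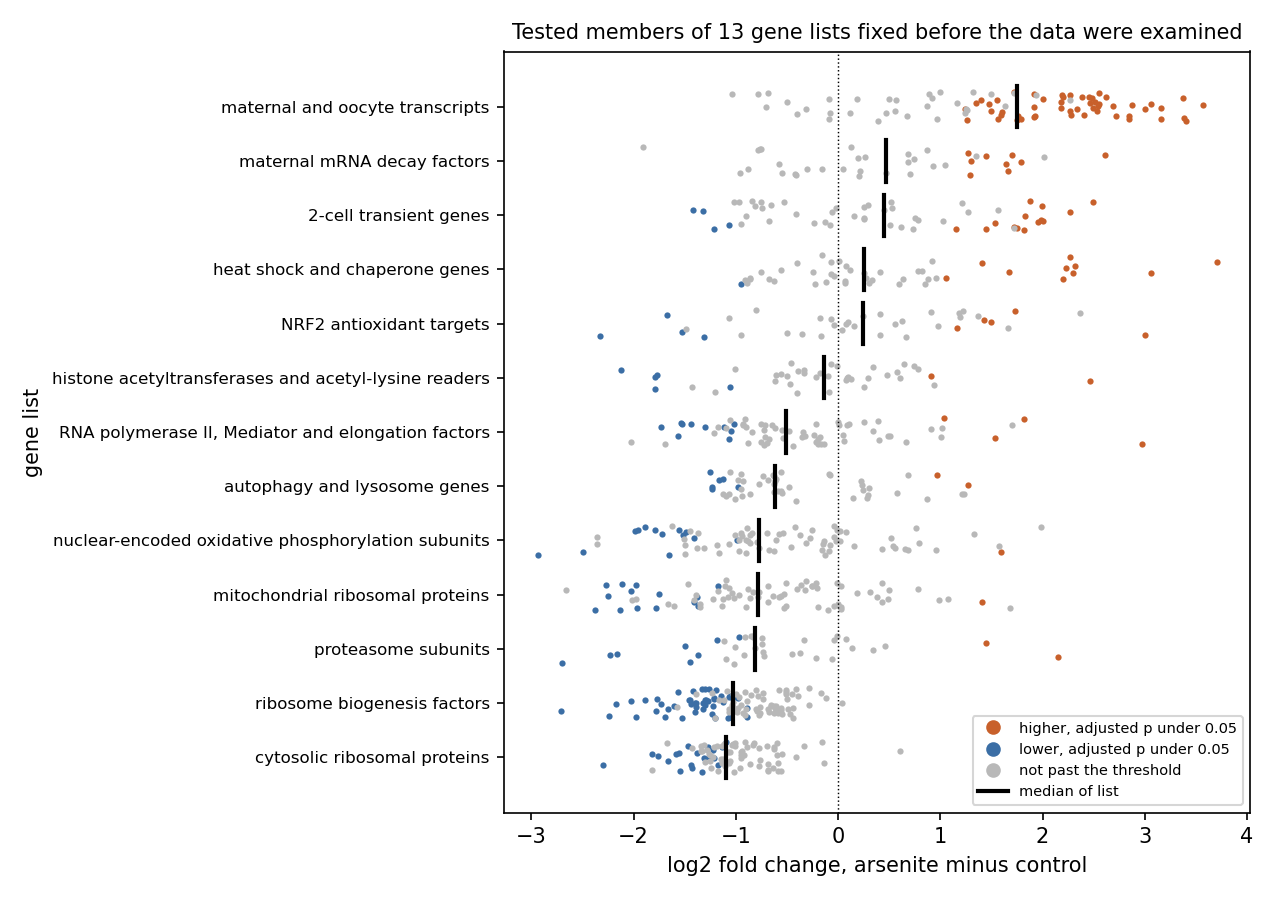
Log2 fold change (arsenite minus control) of each tested member of 13 gene lists, with 1 point per gene, coloured where higher or lower past an edgeR adjusted p of 0.05 and grey otherwise, and a black bar at the list median. The medians were 1.75 for maternal and oocyte transcripts, −1.03 for ribosome biogenesis factors and −1.09 for cytosolic ribosomal proteins.

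Of 111 tested ribosome biogenesis factors 47 fell and 0 rose, while 0 rose and 59 fell adjusted over the list alone. Rpf2 (chromosome 10, 40223246 to 40247039) fell by 2.24 ± 0.32 on the log2 scale (SE, edgeR adjusted p = 0.00463). Utp11, of the small-subunit processome (chromosome 4, 124678232 to 124693610), fell from 225 ± 17.8 to 60.8 ± 6.85 CPM (SD, n = 3 each, edgeR adjusted p = 0.00485). This list had a median of −1.03 and camera passed (adjusted p = 7.99e-17). It did not pass at an adjusted p = 0.0642 with an estimated correlation. Without control replicates 1, 2 and 3 in turn 19, 30 and 7 members fell, and without arsenite replicates 1, 2 and 3 in turn 5, 49 and 29.

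Of 85 tested cytosolic ribosomal protein genes 20 fell and 0 rose, while 0 rose and 25 fell adjusted over the list alone. Rpl14 (chromosome 9, 120571517 to 120574653) fell from 180.0 ± 5.52 to 36.5 ± 10.4 CPM and Rpl5 from 372 ± 40.3 to 110.1 ± 6.86 CPM (SD, n = 3 each, edgeR adjusted p = 0.00463 and 0.00509). These genes had a median of −1.09, past the threshold by camera (adjusted p = 7.86e-13) but not at an adjusted p = 0.453 with an estimated correlation. With the block 62 members fell. Omitting control replicates 1, 2 and 3 in turn gave 8, 10 and 6 falls, and omitting arsenite replicates gave 6, 13 and 54. The share of counts from these genes (2.18% in controls, 0.944% with arsenite) and from Rn45s (0.997% and 0.450%) was lower in the same libraries, the latter with overlapping groups. Poly(A) libraries need not measure Rn45s, a ribosomal RNA precursor, in proportion to its amount.

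Some genes for mitochondria and protein turnover were also lower, in 3 lists whose camera calls were lost at an adjusted p = 0.453 with an estimated correlation. Of 79 mitochondrial ribosomal proteins 14 fell and 1 rose, while 2 rose and 19 fell adjusted over the list alone. Mrpl20 and Mrps24 fell by 1.97 ± 0.34 and 2.27 ± 0.44 on the log2 scale (SE, edgeR adjusted p = 0.0069 and 0.0101). Of 79 nuclear-encoded subunits of oxidative phosphorylation 13 fell and 1 rose, while 1 rose and 13 fell adjusted over the list alone. Ndufa12, of complex I, and Atp5o, of ATP synthase, fell by 2.93 ± 0.50 and 1.56 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.00689 and 0.0105). Without control replicate 3 Mrps24 and Atp5o lost their calls (edgeR adjusted p = 0.0503 and 0.0521). Of 35 proteasome subunits 8 fell and 2 rose, while 2 rose and 15 fell adjusted over the list alone. Psma6, of the core particle (chromosome 12, 55384222 to 55418459), fell from 449.9 ± 26.8 to 96.0 ± 30.0 CPM and Psmd7, of the regulatory particle, from 382 ± 120.0 to 85.1 ± 36.5 CPM (SD, n = 3 each, edgeR adjusted p = 0.00463 and 0.00729). The medians were −0.78, −0.77 and −0.81, and the camera adjusted p = 3.16e-06, 8.36e-06 and 0.000652.

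Members that rose against these lists were chosen after their values were seen. They were Mrpl48, Sdhc of complex II, and the proteasome assembly chaperones Psmd9 and Psmd10, with log2 fold changes of 1.41 ± 0.33, 1.59 ± 0.49, 1.45 ± 0.41 and 2.15 ± 0.38 (SE). Each lost its edgeR call without control replicate 3 (highest adjusted p over the libraries left out = 0.1, 0.249, 0.147 and 0.0503). Mrpl48, Sdhc and Psmd9 also lost theirs without control replicate 1 or arsenite replicate 1, Mrpl48 and Sdhc without control replicate 2, Sdhc and Psmd9 without arsenite replicate 2, and Psmd9 without arsenite replicate 3. Falls with the block numbered 25 for mitochondrial ribosomal proteins, 24 for oxidative phosphorylation and 17 for the proteasome. Without control replicates 1, 2 and 3 in turn the falls numbered 10, 11 and 1 in the first list, 9, 7 and 1 in the second and 5, 6 and 4 in the third. Without arsenite replicates 1, 2 and 3 in turn they numbered 6, 11 and 13, then 3, 12 and 12, then 5, 9 and 6.

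Of 53 tested genes of the transient 2-cell program 14 rose, 4 fell and 35 did not pass, while 16 rose and 5 fell adjusted over the list alone. Zscan4d (chromosome 7, 11161643 to 11166148), of a family that marks the 2-cell stage, rose from 149 ± 27.5 to 430.3 ± 138 CPM and Zscan4f from 135 ± 22.5 to 543 ± 309.6 CPM (SD, n = 3 each, edgeR adjusted p = 0.0131 and 0.0125). Zscan4b and Usp17la, a deubiquitinase gene, rose by 1.83 ± 0.37 and 2.49 ± 0.50 on the log2 scale (SE, edgeR adjusted p = 0.0117 and 0.0117). Copies of Zscan4 and Usp17l are near-identical, so values of single copies are uncertain. The 4 that fell, chosen after their values were seen, were Fbxo15, Bex6, Trim43c and Obox6, with log2 fold changes of −1.32 ± 0.28, −1.42 ± 0.34, −1.06 ± 0.31 and −1.21 ± 0.38 (SE). Zfp352 averaged 134 ± 40.6 CPM in controls and 223 ± 35.0 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.117). The list median was 0.45 and camera did not pass (adjusted p = 0.259).

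Calls in the 2-cell list were lost when single libraries were left out. Without control replicate 3, Zscan4b, Zscan4d, Zscan4f and Usp17la lost theirs (edgeR adjusted p = 0.0624, 0.072, 0.062 and 0.0586). Fbxo15 lost its call without arsenite replicate 1, and Bex6, Trim43c and Obox6 without that library or control replicates 2 or 3 (highest edgeR adjusted p = 0.0697, 0.0846, 0.146 and 0.151). Trim43c and Obox6 also lost theirs without control replicate 1 or arsenite replicate 3. Rises without control replicates 1, 2 and 3 in turn numbered 6, 10 and 0, and falls 2, 2 and 1. Rises without arsenite replicates 1, 2 and 3 in turn numbered 8, 13 and 9, and falls 0, 7 and 4. With the block 14 rose and 7 fell.

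**Figure D3:**
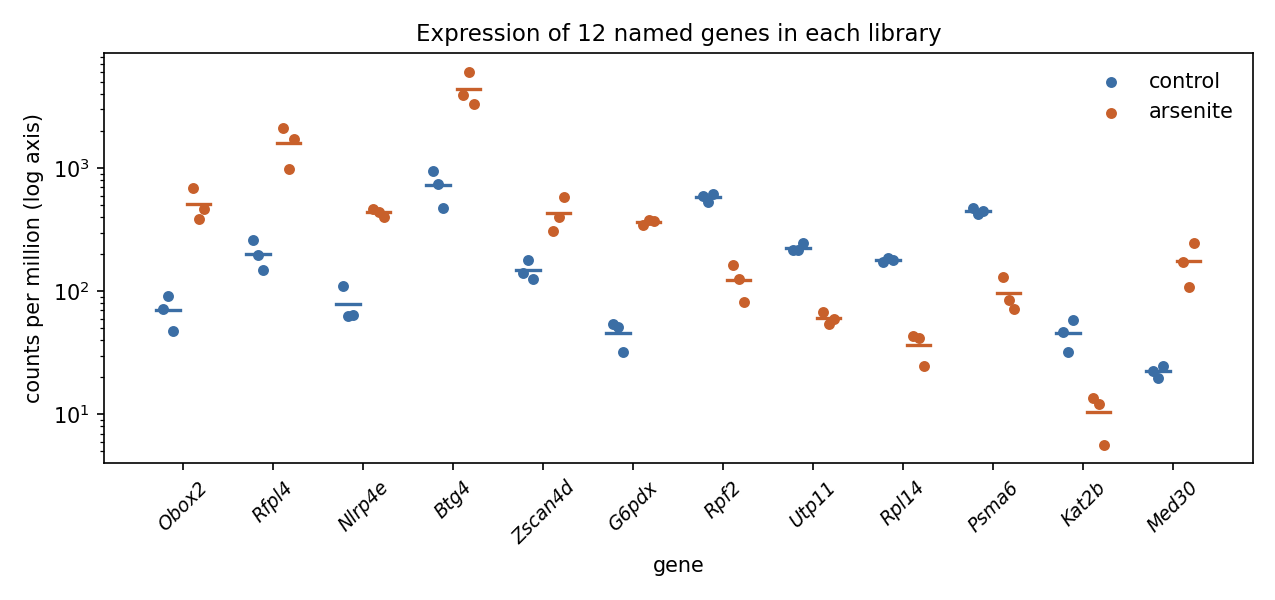
CPM, on a log axis, of 12 genes in each library, with 1 point per library and a bar at the mean of each group of 3. All arsenite points lie above all control points for Obox2, Rfpl4, Nlrp4e, Btg4, Zscan4d, G6pdx and Med30, and below them for Rpf2, Utp11, Rpl14, Psma6 and Kat2b.

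Of 37 tested targets of the antioxidant regulator NRF2 5 rose and 4 fell, while 5 rose and 5 fell adjusted over the list alone. G6pdx, the dehydrogenase that makes NADPH in the pentose phosphate pathway (chromosome X, 74409483 to 74428880), rose from 45.8 ± 12.1 to 367 ± 20.8 CPM (SD, n = 3 each), a log2 fold change of 3.00 ± 0.31 (SE, edgeR adjusted p = 0.00389). Bach1, a repressor of NRF2 targets, fell by 1.67 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 0.0105). Me1, which also makes NADPH, rose by 1.43 ± 0.31 and Pgd, which acts after G6pdx, fell by 1.31 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.0147 and 0.0183). Both lost their calls without control replicate 3 or arsenite replicate 1 (highest edgeR adjusted p = 0.0662 and 0.0698). Hmox1, which arsenite induces in many cells, averaged 2.57 ± 3.11 CPM in controls and 5.87 ± 3.23 CPM with arsenite, with overlapping groups (SD, n = 3 each, edgeR adjusted p = 0.505). Its log2 fold change of 1.18 ± 1.16 (SE) became 0.50 without control replicate 3 and 2.74 without control replicate 2. The list median was 0.24 and camera did not pass (adjusted p = 0.668). Without control replicates the rises numbered 3, 2 and 1 and the falls 2, 2 and 1. Without arsenite replicates they numbered 1, 4 and 3 and 1, 4 and 2.

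The metallothioneins Mt1 and Mt2, which bind metals, had log2 fold changes of −1.31 ± 0.76 and −1.07 ± 0.71 (SE), with overlapping groups and no edgeR call (adjusted p = 0.251 and 0.313). With the block both passed on the lower side (edgeR adjusted p = 0.00669 and 0.0219). They also passed without arsenite replicate 3, at log2 fold changes of −3.07 and −2.53 (edgeR adjusted p = 0.0127 and 0.0254). Without control replicate 3 the log2 fold changes of Mt1 and Mt2 were −0.81 and −0.55. Of the 6 tested members of their list 0 rose and 0 fell by edgeR (0 at an unadjusted p under 0.05), and 0 rose and 0 fell adjusted over the list alone, while 2 fell with the block and 2 without arsenite replicate 3 (median −0.24, camera adjusted p = 0.436). Of 25 genes of arsenic uptake, methylation and one-carbon metabolism 2 rose and 3 fell, while 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.692). Their median was −0.09, of either sign over the alternatives (−0.55 to 0.51), and 0.16 with the block, where 3 rose and 5 fell. Pemt, which uses S-adenosylmethionine to make phosphatidylcholine, fell from 216 ± 91.3 to 48.5 ± 7.69 CPM (SD, n = 3 each, edgeR adjusted p = 0.00599). Rises in that list without control replicates in turn numbered 1, 1 and 0, and falls 1, 1 and 1. Without arsenite replicates in turn they numbered 0, 2 and 1 and 2, 2 and 2.

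Of 45 heat shock and chaperone genes 10 rose and 1 fell, while 11 rose and 3 fell adjusted over the list alone. Hspa2, of the HSP70 family, rose by 3.70 ± 0.61 and Hsbp1, which binds heat shock factor, by 1.67 ± 0.29 on the log2 scale (SE, edgeR adjusted p = 0.00604 and 0.00729). The 1 that fell was Dnajb6, chosen after its values were seen, which fell by 0.95 ± 0.29 on the log2 scale (SE) and lost its call in each fit with a library left out except that without arsenite replicate 2 (highest edgeR adjusted p = 0.153). The median log2 fold change was 0.25 and camera did not pass (adjusted p = 0.259). With the block 4 members fell, and without arsenite replicate 2, 2 fell. Rises without control replicates in turn numbered 4, 8 and 3, and without arsenite replicates 3, 9 and 8.

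Of 47 genes of the integrated stress and unfolded protein responses 4 rose and 1 fell, while 4 rose and 1 fell adjusted over the list alone. Ddit3, which encodes CHOP, and Eif2ak4, the amino acid sensor GCN2, rose by 2.51 ± 0.48 and 1.92 ± 0.34 on the log2 scale (SE, edgeR adjusted p = 0.00974 and 0.00794). Both lost their calls without control replicate 3 (edgeR adjusted p = 0.0557 and 0.0517), where 0 members rose and 0 fell. The list median was −0.03, of either sign over the alternatives (−0.15 to 0.06), its mean 0.09 and its camera direction upward (adjusted p = 0.879), and with the block 6 rose and 5 fell. Of 34 p53 targets and DNA damage genes 1 rose and 2 fell, while 0 rose and 0 fell adjusted over the list alone. Their median was 0.03, of either sign over the scalings and other alternatives (−0.13 to 0.21), their mean 0.04 and their camera direction downward (adjusted p = 0.879). Aen and Tigar fell by 1.03 ± 0.31 and 1.56 ± 0.40 on the log2 scale (SE, edgeR adjusted p = 0.0462 and 0.0256). Aen lost its call whichever library was left out, and Tigar without control replicate 2 or 3 or arsenite replicate 1 or 3 (highest edgeR adjusted p = 0.129 and 0.109). With the block 2 p53 targets rose and 4 fell. Their rises without control replicates in turn numbered 0, 0 and 0 and without arsenite replicates 0, 0 and 0, and their falls 1, 0 and 0 and 0, 1 and 2.

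The title of the series names histone acetylation. The chromatin lists give RNA levels of enzymes, readers and partners, and measure neither acetylation nor protein. Of 40 histone acetyltransferases and acetyl-lysine readers 5 fell and 2 rose, while 2 rose and 5 fell adjusted over the list alone (median −0.14, camera adjusted p = 0.301). Kat2b, the acetyltransferase PCAF (chromosome 17, 53566774 to 53672721), fell from 45.7 ± 13.2 to 10.5 ± 4.18 CPM (SD, n = 3 each, edgeR adjusted p = 0.0128). Tada2a, an adaptor in complexes with Kat2b, and Ing4 fell by 1.77 ± 0.42 and 1.79 ± 0.48 on the log2 scale (SE, edgeR adjusted p = 0.0202 and 0.0322). Cited2, which binds CBP and p300, rose by 2.47 ± 0.71 on the log2 scale (SE, edgeR adjusted p = 0.0385). The others, chosen after their values were seen, were Brd9 and Sgf29, which fell by 1.06 ± 0.31 and 1.79 ± 0.52, and Ncoa2, which rose by 0.91 ± 0.28 on the log2 scale (SE). Brd9 and Ncoa2 lost their edgeR calls whichever library was left out, and Sgf29 kept its call only without arsenite replicate 3 (highest adjusted p = 0.12, 0.203 and 0.107). Ep300 and Crebbp, which acetylate H3 lysine 27, had log2 fold changes of −0.61 ± 0.36 and 0.35 ± 0.26 (SE) and did not pass (edgeR adjusted p = 0.26 and 0.378). Ep300 passed on the lower side with the length and GC trend removed and the block together, at −0.65 (adjusted p = 0.0493). Kat2b, Tada2a and Ing4 lost their calls without control replicate 3, the last 2 also without arsenite replicate 1, and Ing4 also without control replicate 2 or arsenite replicate 3 (highest edgeR adjusted p = 0.0616, 0.0766 and 0.114). Cited2 lost its call in all but the fit without control replicate 2, where its log2 fold change was 3.75 (highest edgeR adjusted p = 0.137). Falls without control replicates in turn numbered 3, 2 and 0 and without arsenite replicates 1, 4 and 3, with 0, 1 and 0 and 0, 0 and 0 rises, and the block gave 4 rises.

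Of 44 histone deacetylases and partners 4 rose and 0 fell, while 3 rose and 0 fell adjusted over the list alone (median 0.01, of either sign over the scalings and other alternatives, −0.12 to 0.16, camera adjusted p = 0.835). Tbl1xr1, a corepressor subunit, and Hdac2 rose by 2.01 ± 0.36 and 1.23 ± 0.29 on the log2 scale (SE, edgeR adjusted p = 0.00754 and 0.0198). Without control replicate 3 both lost their calls (edgeR adjusted p = 0.0505 and 0.106), and Hdac2 also without control replicate 1 or arsenite replicate 1 or 2. With a trend on length and GC content removed Hdac2 had a log2 fold change of 0.78 and no call (adjusted p = 0.0814). Of 57 DNA and histone methylation enzymes 7 fell and 1 rose, while 1 rose and 7 fell adjusted over the list alone (median −0.24, camera adjusted p = 0.259). Ehmt1, a histone H3 lysine 9 methyltransferase, fell by 1.44 ± 0.31 and Uhrf1, a partner of Dnmt1, rose by 1.46 ± 0.31 on the log2 scale (SE, edgeR adjusted p = 0.0139 and 0.0133). Both lost their calls without control replicate 3, and Uhrf1 without arsenite replicate 1 (highest edgeR adjusted p = 0.055 and 0.0641). Deacetylase rises without control replicates in turn numbered 1, 3 and 0 and without arsenite replicates 1, 2 and 3, and 2 fell without arsenite replicate 2. Methylation enzyme falls numbered 2, 5 and 0 and 1, 9 and 2. With the block 6 deacetylase genes rose and 2 fell, and 5 methylation enzymes rose.

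Of 68 RNA polymerase II, Mediator and elongation factors 10 fell and 4 rose, while 4 rose and 12 fell adjusted over the list alone. Med30, a Mediator subunit (chromosome 15, 52712445 to 52730431), and Gtf2b, which encodes TFIIB, rose against the list median of −0.51. Med30 went from 22.4 ± 2.51 to 176 ± 69.7 CPM and Gtf2b from 56.6 ± 9.11 to 200.1 ± 30.8 CPM (SD, n = 3 each, edgeR adjusted p = 0.00416 and 0.00556). The list passed camera (adjusted p = 0.00893), a call lost at an adjusted p = 0.453 with an estimated correlation. Of 48 autophagy and lysosome genes 6 fell and 2 rose, while 3 rose and 10 fell adjusted over the list alone (median −0.62). Camera passed (adjusted p = 0.0175) but not at an adjusted p = 0.453 with an estimated correlation, nor without control replicate 1 (adjusted p = 0.0588). Ctsa, a lysosomal protease, fell by 1.23 ± 0.30 and Atp6v1h, a proton pump subunit, rose by 1.28 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.0219 and 0.0206). Ctsa kept its call only without arsenite replicate 2, and Atp6v1h lost its own without control replicate 2 or 3 or arsenite replicate 1 (highest edgeR adjusted p = 0.0888 and 0.109). With the block 19 polymerase and 14 autophagy list members fell. Polymerase list falls without control replicates in turn numbered 3, 4 and 0 and without arsenite replicates 1, 10 and 7, and autophagy list falls 1, 1 and 0 and 0, 8 and 2.

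Of 42 pluripotency and lineage factors 4 fell and 2 rose, while 3 rose and 8 fell adjusted over the list alone (median −0.47, camera adjusted p = 0.259). Dppa5a fell from 1719 ± 777 to 387 ± 297 CPM (SD, n = 3 each) and Nfya, a subunit of the factor NF-Y, rose by 1.33 ± 0.31 on the log2 scale (SE, edgeR adjusted p = 0.0241 and 0.019). Both lost their calls without control replicate 3 or arsenite replicate 1, and Nfya without control replicate 2 (highest edgeR adjusted p = 0.0937 and 0.105). Pou5f1 averaged 2.20 ± 0.230 CPM in controls and 7.93 ± 3.60 CPM with arsenite and Nanog 1.19 ± 0.666 CPM in controls and 1.38 ± 0.907 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.0815 and 0.913). With the block 8 members fell, without control replicates in turn 2, 1 and 1, and without arsenite replicates 0, 4 and 1. Of 62 cell cycle and mitosis genes 7 rose and 5 fell, while 7 rose and 5 fell adjusted over the list alone (median −0.13, camera adjusted p = 0.351). Ccne2 and Ccnb2, cyclins of S phase entry and mitosis, rose by 1.80 ± 0.34 and 1.44 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 0.00952 and 0.0193). Without control replicate 3 both lost their calls (edgeR adjusted p = 0.0503 and 0.0913), at log2 fold changes of 1.83 and 1.10. Ccnb2 also lost its call without control replicate 1 or arsenite replicate 1. Cell cycle rises without control replicates in turn numbered 2, 2 and 0 and without arsenite replicates 1, 6 and 2, and falls 0, 4 and 0 and 0, 10 and 2. The block gave 14 falls.

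Of 24 genes of the glycolysis list, which also holds Dlat of pyruvate dehydrogenase, 3 rose and 0 fell, while 2 rose and 0 fell adjusted over the list alone (median 0.04, of either sign over the scalings and other alternatives, −0.17 to 0.21, camera adjusted p = 0.668). Dlat and Ldhb rose by 1.64 ± 0.37 and 1.95 ± 0.49 on the log2 scale (SE, edgeR adjusted p = 0.0176 and 0.0249), calls lost without control replicate 3 or arsenite replicate 1 (highest adjusted p = 0.0847 and 0.118), where 0 members rose. Dlat also lost its call without control replicate 2 and Ldhb without control replicate 1, and the block gave 5 rises and 2 falls. Of 12 immediate early genes 1 rose and 0 fell, while 0 rose and 0 fell adjusted over the list alone (median 1.14). Camera did not pass (adjusted p = 0.0626), but did without control replicate 2 or 3 (adjusted p = 0.00536 and 0.00891) and without arsenite replicate 1 or 3 (adjusted p = 0.0153 and 0.0393). Klf6, the member that rose, had a log2 fold change of 2.34 ± 0.70 (SE, edgeR adjusted p = 0.0449) and kept its call only without control replicate 2, at 3.74 (highest adjusted p = 0.146). Ier5 averaged 7.44 ± 1.90 CPM in controls and 21.5 ± 9.85 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.0541) and passed with the block (adjusted p = 0.0294), where 3 members rose. Rises in this list without control replicates in turn numbered 0, 2 and 0 and without arsenite replicates 0, 0 and 0. Of 301 genes named Zfp, most of them zinc finger genes, 15 rose and 12 fell, while 4 rose and 5 fell adjusted over the list alone (median 0.22, −0.01 with the length and GC trend removed, camera adjusted p = 0.436). Zfp292 fell from 80.8 ± 26.0 to 7.62 ± 3.09 CPM and Zfp277 rose from 13.6 ± 2.66 to 59.4 ± 1.78 CPM (SD, n = 3 each, edgeR adjusted p = 0.00416 and 0.00552). Zfp rises without control replicates in turn numbered 9, 5 and 3 and without arsenite replicates 2, 11 and 10, falls 5, 7 and 2 and 4, 19 and 7, and the block gave 29 and 26.

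Markers of other cells were low or mixed in direction. Of 6 cumulus and granulosa markers 1 rose and 0 fell, while 1 rose and 0 fell adjusted over the list alone. The 1 was Cyp11a1, the first enzyme of steroid synthesis, with 0 counts in controls and 62 with arsenite. Against a floor of 3 counts over the control group it was at least 20.7-fold higher (edgeR adjusted p = 0.0198), where an exact 95% counting interval, which also covers the error of the 62 counts, began at 16.3-fold, and it kept its call only without arsenite replicate 2 (highest adjusted p = 0.0727). Tnfaip6 averaged 0.444 ± 0.674 CPM in controls and 3.55 ± 1.49 CPM with arsenite and Amhr2, chosen after its values were seen, 34.5 ± 1.80 CPM in controls and 26.5 ± 6.45 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.127 and 0.462). The list median was 1.27, also with Cyp11a1 at its bound, but ran from −0.36 to 2.63 over the alternatives, the lowest with a mean count of at least 50. Of the camera fits with a library left out, that without arsenite replicate 1 passed (adjusted p = 0.0267, against 0.217 with all libraries). Of 3 sperm and spermatid markers, too few for camera, 1 rose and 0 fell, while 1 rose and 1 fell adjusted over the list alone. Odf2, also a centrosome gene, rose from 65.1 ± 18.0 to 134 ± 24.2 CPM (SD, n = 3 each, edgeR adjusted p = 0.0445), a call lost whichever library was left out (highest adjusted p = 0.181). Ldhc averaged 25.9 ± 6.06 CPM in controls and 11.2 ± 5.17 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.0913) and passed on the lower side with the block (adjusted p = 0.0346). Of 4 blood, fibroblast and oviduct markers 0 rose and 0 fell by edgeR (0 at an unadjusted p under 0.05, against 4269 of all genes tested), and 0 rose and 0 fell adjusted over the list alone. Pecam1 averaged 13.1 ± 4.13 CPM in controls and 7.26 ± 1.87 CPM with arsenite and Ovgp1 9.09 ± 3.20 CPM in controls and 4.80 ± 2.40 CPM with arsenite (SD, n = 3 each, edgeR adjusted p = 0.251 and 0.323).

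Under the rule for named genes the 6 largest rises included Clec12a, a lectin receptor of myeloid cells (chromosome 6, 129349783 to 129365303), which rose from 2.14 ± 1.33 to 51.5 ± 16.5 CPM (SD, n = 3 each, edgeR adjusted p = 0.00392). Sertad3 rose from 0.530 ± 0.631 to 27.3 ± 8.25 CPM and Ildr1, of tricellular junctions, from 0.232 ± 0.201 to 11.9 ± 1.89 CPM (SD, n = 3 each, edgeR adjusted p = 0.00534 and 0.00552). Kcnh5, a potassium channel gene, had 2 counts in controls and 276 with arsenite, a ratio of 138 with an exact 95% counting interval of 37.8 to 1145 (edgeR adjusted p = 0.0071). Both control counts were in control replicate 2, without which the fitted log2 value went from 6.94 to 9.52 against controls at 0, which is no bound. Among the 6 largest falls Klhl10, a ubiquitin ligase adaptor known from spermatids (chromosome 11, 100441128 to 100457027), fell from 47.1 ± 5.36 to 1.51 ± 0.927 CPM (SD, n = 3 each, edgeR adjusted p = 0.00392). Ocm, the calcium-binding oncomodulin, fell from 67.5 ± 11.97 to 3.79 ± 2.87 CPM and Krt28, a keratin, from 61.6 ± 12.2 to 2.11 ± 2.19 CPM (SD, n = 3 each, edgeR adjusted p = 0.00416 and 0.00749). Rcc1l, a mitochondrial ribosome assembly factor, fell from 11.1 ± 1.92 to 0.410 ± 0.238 CPM (SD, n = 3 each, edgeR adjusted p = 0.00551). These 8 kept their calls whichever library was left out. Gstm6, Trpc4, Dynap and Chrna10 had log2 fold changes of 4.93 ± 1.24, 4.65 ± 1.17, −4.31 ± 1.16 and −4.19 ± 1.02 (SE) and lost their calls without control replicate 3 or arsenite replicate 1 (highest edgeR adjusted p = 0.0974, 0.0819, 0.138 and 0.126). Without control replicate 1, which held all 8 control counts of Gstm6 and all 13 of Trpc4, their fitted values were 9.35 and 9.75 against controls at 0, which are no bounds. Dynap ran from −3.40 without control replicate 1 to −6.95 without arsenite replicate 2. Chrna10 ran from −2.90 without control replicate 2 to −5.74 without arsenite replicate 2. Dynap also lost its call without control replicate 1, the other 3 without control replicate 2, Trpc4 without arsenite replicate 2, and the other 3 without arsenite replicate 3.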

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

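Keeping the date rows and removing the length and GC trend, alone or with the replicate block, were tests chosen after the result was seen. The 2101 calls (914 lower) became 3268 (1586 lower) with the replicate block, of which 2068 were among the 2101. They became 3313 (1557 lower) with DESeq2, 3408 (1642 lower) with voom quality weights, and 3541 (2050 lower) with the trend removed and the replicate block, while the trend alone gave 2584 (1448 lower). Leaving out 1 library, so fewer samples, gave 405 to 2002 calls, 217 to 930 higher and 180 to 1072 lower. With an estimated correlation ribosome biogenesis had an adjusted p of 0.0642 and the maternal, cytosolic and mitochondrial ribosomal, oxidative phosphorylation, proteasome, polymerase II and autophagy lists 0.453. Fry asks whether a list's genes move one way on balance, not, as camera does, whether they differ from other genes. By it cytosolic ribosomal proteins (0.0888) and oxidative phosphorylation (0.098) did not pass, and decay factors (0.0487), heat shock genes (0.0449), cumulus markers (0.0449) and acetyltransferases (0.0478) did. Immediate early genes passed with no count filter (0.0134), a CPM filter (0.0142), the trend removed (0.0123) and that with the replicate block (0.00752), in a range over all alternatives from 0.00536 to 0.453. With 1 library left out the adjusted p ran from 0.00536 to 0.190 for them, 0.00771 to 0.0588 for autophagy genes and 0.0267 to 0.282 for cumulus markers. Nanog, near the floor, went from 0.20 to −0.0540 with voom, −0.134 with the trend removed, −0.296 with that and the replicate block, and −0.247 to 0.663 with 1 library left out. With library size only Klf6, Odf2 and Cited2 lost their calls (edgeR adjusted p = 0.0756, 0.0607 and 0.0651), with voom Dynap and Chrna10 did (0.074 and 0.0977), and with no count filter Aen did (0.0554). With DESeq2 Pou5f1, Ier5 and Ldhc gained calls (0.0453, 0.0222 and 0.0401), and with voom quality weights Mt1, Mt2, Ier5 and Ldhc did (0.0128, 0.0402, 0.0463 and 0.0268). With the trend removed Hdac2 and Klf6 lost theirs (0.0814 and 0.111) and Pou5f1, Ier5 and Ldhc gained them (0.0456, 0.0472 and 0.0486), as did Ep300 with the trend removed and the replicate block (0.0493). The cause was not tested. Among the genes taken by the naming rule and the camera list tests, the replicate block changed the calls of Mt1, Mt2, Ier5 and Ldhc and no other call. Over all alternatives, those above included, 45 values of counts stayed within 1.5 times. For lists 474 values kept their call, or its absence. For named genes 1529 values kept that and their direction. A list that changed direction without a call in either fit was not counted as reversed, unlike a named gene. By over 1.5 times 9 values of counts rose and 12 fell. Of list values 13 gained and 11 lost a call. Of named gene values 22 gained a call, 113 lost one and 6, all of Nanog, reversed. No symbol of the table matched the pattern for mitochondrially encoded genes, so that alternative left out the 20 most abundant genes alone. At this spread and depth edgeR recovered 5.6% of simulated 2-fold changes, in runs with 200 changed genes. Recovery depends on how many genes change, and 2101 were called here, so the share in the real fit may differ.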

Other observations

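The family scan, the test of the Zscan4 median, the tests of the Zscan4 and Usp17l sums, which were judged apart only once their values were seen, the comparison of list medians between splits, and the removal of the length and GC trend were tests chosen after the result was seen, although the prediction for that trend was written before its result.

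Gene families outside the fixed lists, taken by the letters that open their symbols, also moved. Of 10 tested Xlr genes, X-linked with near-identical copies, 7 rose and 0 fell by edgeR, with a median log2 fold change of 1.54 (two-sided Fisher's exact test against all tested genes, adjusted p = 0.0019 over 312 tests of 156 families). Of 9 Exosc genes, subunits of the RNA exosome, 5 fell and 0 rose (median −1.46, adjusted p = 0.0154). Of 9 Emc genes, of a membrane protein insertase, 5 fell and Emc2 rose (adjusted p = 0.0154), and of 15 Timm genes, of mitochondrial protein import, 6 fell and Timm21 rose (adjusted p = 0.0255). Genes of a family are not independent, which these p-values ignore.

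Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, itself, with 2101 genes by edgeR against at most 0 in the others (4269 against 62 to 467 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. All splits were fitted without the replicate block. For gene lists 3 splits gave as many, the real one calling 8 and the highest other 9, and again 10 splits are too few for a share under 0.05. That split set control 1, control 2 and arsenite 3 against the rest and parts all 3 numbered pairs, as the real one does, and the remaining splits that do so called 2 and 7. Each other split mixes the groups and so keeps part of the arsenite difference, which means that its list calls need not be false. They can also come from spread between libraries. The maternal median lay 1.67 from that of all genes in the real split and at most 1.00 in the others. Ribosome biogenesis had 1.10 and at most 0.47. Cytosolic ribosomal proteins had 1.16 and at most 1.10, and oxidative phosphorylation 0.84 and at most 0.81. For these 2 lists another split nearly matched the real one, more than part of the arsenite difference alone would give. Mitochondrial ribosomal proteins had 0.85 and at most 0.48, the proteasome 0.88 and at most 0.53, polymerase II 0.58 and at most 0.32, and autophagy 0.69 and at most 0.47. In these lists, and in the maternal and ribosome biogenesis lists, the highest other value also lay above that part. Spread between libraries thus enters these medians too. For 2-cell genes and cumulus markers, without a camera call, another split lay further off (0.51 against 0.38 and 1.41 against 1.20).

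The medians of maternal transcripts and ribosome biogenesis factors lay 2.77 apart on the log2 scale, and 2.31 to 3.22 with 1 library left out. Without the 20 most abundant genes the gap was 2.83, and a shift by a few abundant genes is 1 factor per library, which cannot part lists. With the length and GC trend removed it was 2.55, which argues against that trend as the whole cause. Oocytes that never activated their genome would lower Zscan4. The 5 tested Zscan4 genes had a median log2 fold change of 1.95 (SD 0.20), with all arsenite libraries above all controls. This rise is not what such a mixture alone would give. The prediction was written once these values were known, so it is no independent test. The near-identical Zscan4 copies are not independent, and all 5 lost their edgeR calls without control replicate 3. Of the whole 2-cell list 32 members were above 0 and 21 below, with 14 rises and 4 falls. A partial mixture, an effect of arsenite on clearing maternal RNA and slower development stay open, as untested hypotheses. Counts of poly(A) libraries also need not follow the amount of maternal RNA.

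Zscan4 and Usp17l genes were higher with arsenite, and their copies share reads. Reads moving between copies would leave a family's sum as it was. The summed Zscan4 genes went from 497 ± 71.6 to 1798 ± 937 CPM (SD, n = 3 each), a log2 ratio of 1.86 against a range of 0.35 among controls. All 5 copies counted here had risen, so their sum had to rise and is no separate test. Reads moving only among these copies would lower some of them, which was not seen. Reads from copies not counted here were not covered. For Usp17l the log2 ratio of sums was 0.75, within the control range of 0.83, although all 3 arsenite sums (lowest 321 CPM) lay above all 3 control sums (highest 290.3 CPM), so a rise and a shift between copies cannot be told apart there.

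A candidate explanation for the genes higher with arsenite is that maternal mRNAs with the cytoplasmic polyadenylation element TTTTAT near the 3' end were kept. Over 11342 genes with a 3' UTR of at least 100 bases (90.1% of those tested), genes with TTTTAT in the last 100 bases differed in mean log2 fold change by −0.0363 from those without it at the same AT content (one-sided permutation p = 0.853, 100000 permutations). Of 6 hexamers with a single A among T it ranked 4, and the highest was TTTATT at 0.01. This argues against the element as a general mark of the genes that rose, as far as annotated 3' ends go. The genes compared were not limited to maternal mRNAs, so an effect confined to those was not tested.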
